A study of Rattus norvegicus with 20 samples.

How the data were processed

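Ovarian RNA of 20 rats was hybridised to 1-colour Agilent rat arrays, and groups were taken from the dose in the labels. Per the labels' protocols, RNA came from entire frozen ovaries, and 100 ng was labelled with Cy3. Each array has 62976 spots, 58717 of them not controls, for 30367 probes. Per the file headers, spot intensity was read with Feature Extraction 11.5.1.1 under protocol GE1_1105_Oct12 on a G2600D scanner, and the processed signal is background-corrected intensity on a linear scale. The deposited table of the series holds the authors' log2 values of the same arrays, and its columns had medians within 0.1 of 0. On probes well above background on every array, deviations from the probe mean correlated with those of the scanner values, with r of 0.946 to 0.991. The baseline of its centring stays unknown. The submitters' normalization steps are not given in the sources used here. Per the labels, replicate 4 at 0.06 mg/kg/day was removed by the submitters as an outlier, and it was not analysed here.

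The files give a transcript accession per probe, matched without version to a table of rat genes of assembly GRCr8; the array design names build rn4, so no coordinates are printed. Of the probes, 18758 had 1 symbol, 0 several and 11609 none here, covering 15715 symbols. Akr1c18 was found under its present symbol Akr1c3 and is printed under the older name.

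Values are log2 of the processed signal minus the 75th percentile over non-control probes of the array. Spots of a probe were averaged, and spots marked as outliers were left out; 32 probes with no remaining spot on some array were dropped. 0 spots were saturated. Probes well above background on at least 4 of the 20 arrays were kept: 23258 probes, 14858 of them named, for 12452 symbols. The number of arrays limits the precision, and the median residual SD was 0.275 log2.

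limma 3.58.1 in R 4.3.3 fitted group means to all 20 arrays, and contrasts of each dose with 0, of doses with each other, over dose order and jointly were tested with Benjamini-Hochberg adjustment at 0.05. Differences are given as log2 of dose minus 0 mg/kg/day with their SE. Lists of genes of steroid and lipid metabolism, ovarian cell types, hormone and growth factor signalling, xenobiotic and stress responses and other cell types, 38 in all, were tested with fry on 1 probe per gene, the brightest. The directional p of fry asks whether the genes of a list move on balance one way. camera with a correlation preset at 0.01 or estimated was run beside it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The lists, the fixed genes, the tests and most alternatives were set before the data were examined.

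The rule for named genes took, per dose, the 10 largest rises and 10 largest falls among genes past the threshold, with a regular symbol and well above background on every array of at least 1 of the 2 groups. Where fewer than 20 passed, as at every dose, genes of smallest p filled the list to 20, given as values that did not pass. 20 fixed genes of ovarian function or exposure were named whatever their values, by their brightest probe, and disagreement between probes is stated. 1 gene taken by the rule at 0.06 mg/kg/day is not reported here. Members of lists named beside a list, and features outside the rule, were chosen after their values were seen.

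For a probe not well above background on a whole group, the fold is a bound. It compares the mean of the brighter group with that of the higher of the probe's own signal and the lowest signal well above background on each array of the dimmer group.

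On simulated data with 200 changed probes among 23258, limma recovered 33.0%, 64.0%, 84.8% and 91.8% of changes of 1.5, 2, 3 and 4-fold at 0.06 mg/kg/day. At 20 it recovered 40.2%, 66.0%, 87.4% and 90.4%, and at 60 42.2%, 71.4%, 89.2% and 93.0%. Of the calls 4.87%, 5.08% and 5.92% were false. The noise was drawn independently for each probe and array, without slide differences or correlation between probes. These rates therefore need not hold for the real arrays. With 1 list shifted 1.5-fold, fry called it in 6, 7 and 7 of 10 simulations at the 3 doses.

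Slide was tested as a batch: 4659 probes differed between the 3 slides in limma, and slide explained 80.6% of the first principal component, which held 25.0% of the variance. Slide holds all 4 groups, so slide was also fitted as a block; those values are given beside the counts, for the signs of the genes of smallest p, and for some of the fixed genes and lists. In the file headers, the fitted slope of the spike-in controls, RNA of known amount added to each sample, is 0 on 9 arrays, 2, 1, 3 and 3 of them at the 4 rising doses, and about 1 on the others. Between these sets limma called 0 probes, with 2805 at an unadjusted p under 0.05, and the set was fitted as a block too. List means were also taken within each slide and without each array. Alternatives were quantile normalization, normexp background correction with an offset of 50, other filters, the deposited log2 table, slide and replicate number as blocks, array weights, another variance model, only the groups compared, 1 probe per gene, and leaving out each array. normexp used the median signal of each spot in place of the mean. The closing section gives their effect.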

Results

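RNA from whole ovaries of 20 female Sprague-Dawley rats was measured on 1-colour Agilent arrays, 1 animal per array. The dams ate a diet with a mixture of brominated flame retardants, compounds added to plastics and textiles, from before mating until weaning on postnatal day 21. The mixture held 52.1% DE-71 and 0.4% DE-79, which are commercial polybrominated diphenyl ether products, 44.2% of the diphenyl ether BDE-209 and 3.3% hexabromocyclododecane. Diets with 0.75, 250 and 750 mg of mixture per kg were meant to deliver 0.06, 20 and 60 mg per kg body weight per day. The daughters were killed on postnatal day 46, so the arrays describe ovaries at that age, some weeks after the feeding ended. There were 5 animals at 0 mg/kg/day, 4 at 0.06, 5 at 20 and 6 at 60, from independent litters per the labels. The 75th percentile of the processed signal ran from 1158 to 1737 over the arrays, and 74.8% to 83.4% of the spots lay well above background. The arrays came on 3 slides, each holding all 4 groups.

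The comparison of each dose with 0 mg/kg/day asks whether perinatal exposure left a trace in ovarian gene expression. At 0.06 mg/kg/day the smallest p belonged to Casp6, an executioner caspase, at -0.37 ± 0.08 log2 (SE), below all 5 controls in 4 of 4 animals. Csf2ra, a receptor chain for a myeloid growth factor, stood at +0.42 ± 0.12 and Endog, a mitochondrial nuclease, at +0.82 ± 0.23. Dnaja1, a heat shock co-chaperone, stood at -0.61 ± 0.18. The largest difference among the 20 genes taken by the rule was C13h1orf116 at +1.60 ± 0.42, above all controls in 4 of 4 animals. None of these passed: limma called 0 of 23258 probes, with 710 at an unadjusted p under 0.05 and 1.00 as the lowest adjusted p. With slide as a block limma also called 0, with 970 at an unadjusted p under 0.05.

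Other genes taken by the rule at 0.06 mg/kg/day were Dmrtc1a, Gstt2, Zc3h12d, Art4, Mdp1 and Trappc6a above the control mean, and Tmem107, Clec2d2l1, Spin2a, Ptger4, Cct8l2, Stam, Tpbg and Zbtb12 below it. A second probe of Zc3h12d had the opposite sign. Zbtb12 was not well above background on the 4 arrays of this dose, which leaves only a bound of at least 1.24-fold lower. Over the 20 genes, the size of the difference ran from 0.33 to 1.60 log2. All 20 kept their sign with slide as a block. Here and at the other doses the genes were picked by p on these same arrays. Neither signs kept nor values beyond all controls therefore test them.

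At 20 mg/kg/day Casp6 again had one of the smallest p, at -0.35 ± 0.08 log2, below all controls in 5 of 5 animals. Its difference was -0.36 at 0.06 and -0.35 at 20 mg/kg/day with slide as a block. Kcnk1, a potassium channel, stood at -1.67 ± 0.43 and Isyna1, the enzyme that makes inositol phosphate from glucose phosphate, at -0.57 ± 0.15, each below all controls in 5 of 5 animals. Fas, a death receptor, stood at +0.71 ± 0.20 and Tnnt2, a troponin of heart muscle, at +0.62 ± 0.17. RT1-T24-2, a class I histocompatibility gene of a family of near-identical copies, stood at +1.99 ± 0.56. None passed: limma called 0 probes, with 1066 at an unadjusted p under 0.05 and a lowest adjusted p of 0.929, and with slide as a block 0 and 1427.

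The remaining genes of the rule at this dose were Lyrm2, Adamts19, Smcr8, Plagl1, Amph, Hpdl, Kiaa0232, Scara5 and Wdr82 above the control mean, and Bcl2l15, Vgll4, St7l, Cyp20a1 and Ly49i4 below it. For Kiaa0232, 1 of 2 other probes had the opposite sign. Differences ran from 0.35 to 1.99 log2 in size, and all 20 genes kept their sign with slide as a block.

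At 60 mg/kg/day Wdr54 stood at -0.44 ± 0.09 log2 and Npy1r, a receptor of neuropeptide Y, at -0.82 ± 0.20, each below all controls in 6 of 6 animals. Lyl1, a transcription factor of blood and endothelial precursors, stood at +0.61 ± 0.15, Dok3 at +0.62 ± 0.15, Tnfaip8l2 at +0.90 ± 0.24 and Igsf6 at +0.84 ± 0.23. Cd7, a lymphocyte antigen, stood at -0.50 ± 0.14 and Mcpt9, a mast cell protease, at -0.55 ± 0.14. Cd274, the ligand PD-L1, was not well above background on the arrays of this dose and is at least 1.70-fold lower there. Tnnt2 stood at +0.63 ± 0.16, close to its value at 20 mg/kg/day. limma called 0 probes, with 1464 at an unadjusted p under 0.05 and a lowest adjusted p of 0.782, and with slide as a block 0 and 1339.

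The others at 60 mg/kg/day were Slbp and Ly49si2 above the control mean, and Gpr37, Pip4k2b, Hey2, Apoc4, Slc25a2, Cdkl1, Fam181b and P3h2 below it. Ly49si2 belongs to a family of natural killer cell receptors with near-identical copies, so its probe can read relatives. Sizes ran from 0.43 to 1.15 log2 over the 20 genes, all of which kept their sign with slide as a block.

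**Figure D1:**
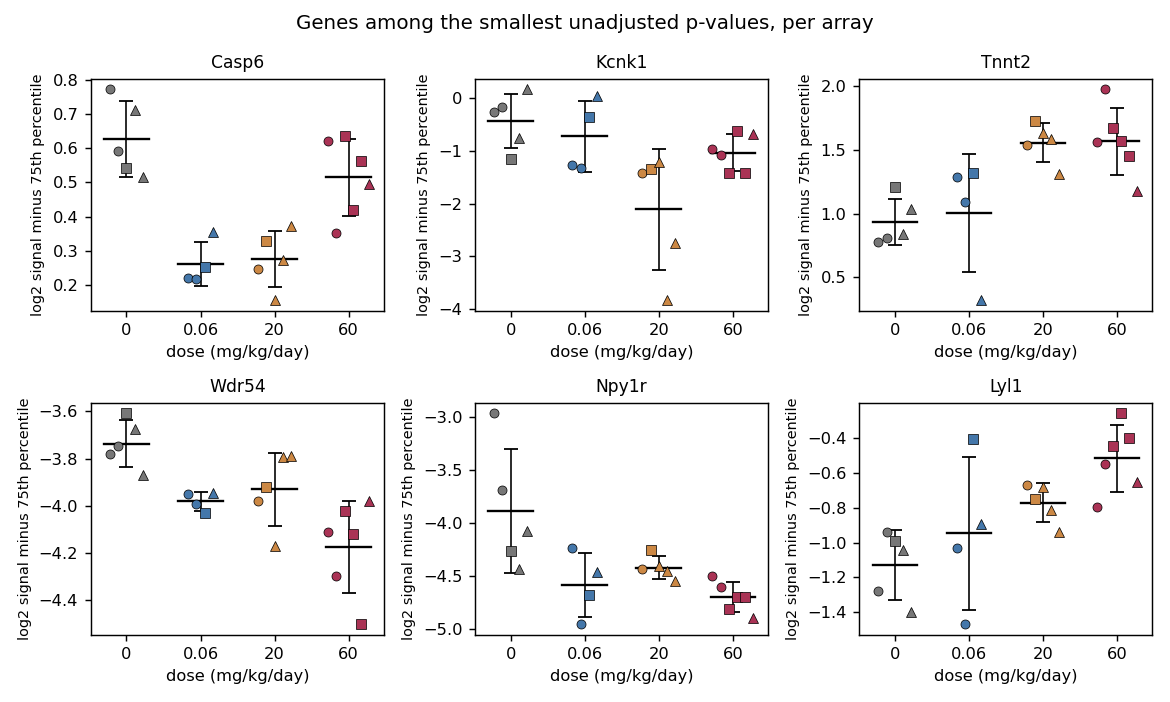
Signal per array for 6 of the genes with the smallest unadjusted p, as log2 minus the 75th percentile of the array, against dose in mg/kg/day (circles, squares and triangles mark slides 1, 2 and 3; lines are means and bars SD). Casp6 lies lower at 0.06 and 20 mg/kg/day, by -0.37 and -0.35 log2, and overlaps the controls at 60.

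Of the 20 genes of ovarian function and exposure fixed before the data were examined, 14 were measured. At 0 mg/kg/day the mean was 6.99 ± 0.26 log2 for Cyp11a1, which cuts the cholesterol side chain, and 4.93 ± 0.36 for Star, which brings cholesterol into mitochondria (SD, n = 5). At 60 mg/kg/day Cyp1b1, an aryl hydrocarbon receptor target that hydroxylates oestradiol, stood at +1.39 ± 0.42 (SE, 95% interval 0.52 to 2.27), above all controls in 5 of 6 animals. Its value was +1.45 with slide as a block, +0.95 ± 0.46 at 0.06 and +0.83 ± 0.44 at 20 mg/kg/day. Inha, the inhibin alpha subunit of granulosa cells, stood at -0.30 ± 0.12, -0.35 ± 0.11 and -0.17 ± 0.11 at the 3 doses. Amh, made by small growing follicles, stood at -0.55 ± 0.40, -0.96 ± 0.38 and -0.37 ± 0.36, the last -0.15 with slide as a block. Esr2, the oestrogen receptor of granulosa cells, stood at -0.48 ± 0.20, -0.43 ± 0.19 and -0.40 ± 0.18, where 1 of its 2 other probes had the opposite sign at 20 mg/kg/day. Esr1 was +0.63 ± 0.25, +0.52 ± 0.24 and +0.26 ± 0.23.

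Adjusted over the list alone, 0 of the 14 genes passed at any dose in limma, the lowest adjusted p being 0.112 at 0.06, 0.0852 at 20 and 0.0502 at 60 mg/kg/day, the last for Cyp1b1. The value at 60 sits at the edge of the threshold: over the 13 genes without Akr1c18, which was at first missed because the table lists it under a newer symbol, it was 0.0466. Unadjusted, 3, 4 and 2 of the genes had p under 0.05. Cyp17a1, the androgen-making enzyme of theca cells, Lhcgr, the receptor of luteinising hormone, and Akr1c18, which inactivates progesterone at the end of luteal life, differed widely between animals of some groups. On the 5 control arrays the SD was 2.60 log2 for Cyp17a1, 1.60 for Lhcgr and 4.84 for Akr1c18. At 20 mg/kg/day it was 3.64, 1.16 and 0.336, and at 60 it was 2.75, 0.945 and 0.628. Akr1c18 thus spread little at these 2 doses. With SE of 1.68 to 1.86 log2 for Cyp17a1 and 1.79 to 1.99 for Akr1c18, a dose difference of several-fold was not detectable. At 60 mg/kg/day Cyp17a1 stood at -0.05 ± 1.68, Lhcgr at -0.72 ± 0.83 and Akr1c18 at +1.65 ± 1.79, and with slide as a block at +0.75, -0.35 and +1.13. Single arrays weigh heavily on these values. Akr1c18 lay at -4.23 on control replicate 5 and at 5.95 to 7.02 on the other controls. Cyp17a1 lay at -2.62 on control replicate 3, against 2.69 to 3.47, and at -3.52 on 60 mg/kg/day replicate 5, against 2.05 to 3.86. Pgr was well above background on 2 arrays, Dio2 on 3, and Cyp1a1 and Thrb on 0, so these were not tested. Cyp19a1 and Cyp2b1 were not analysed here.

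**Figure D2:**
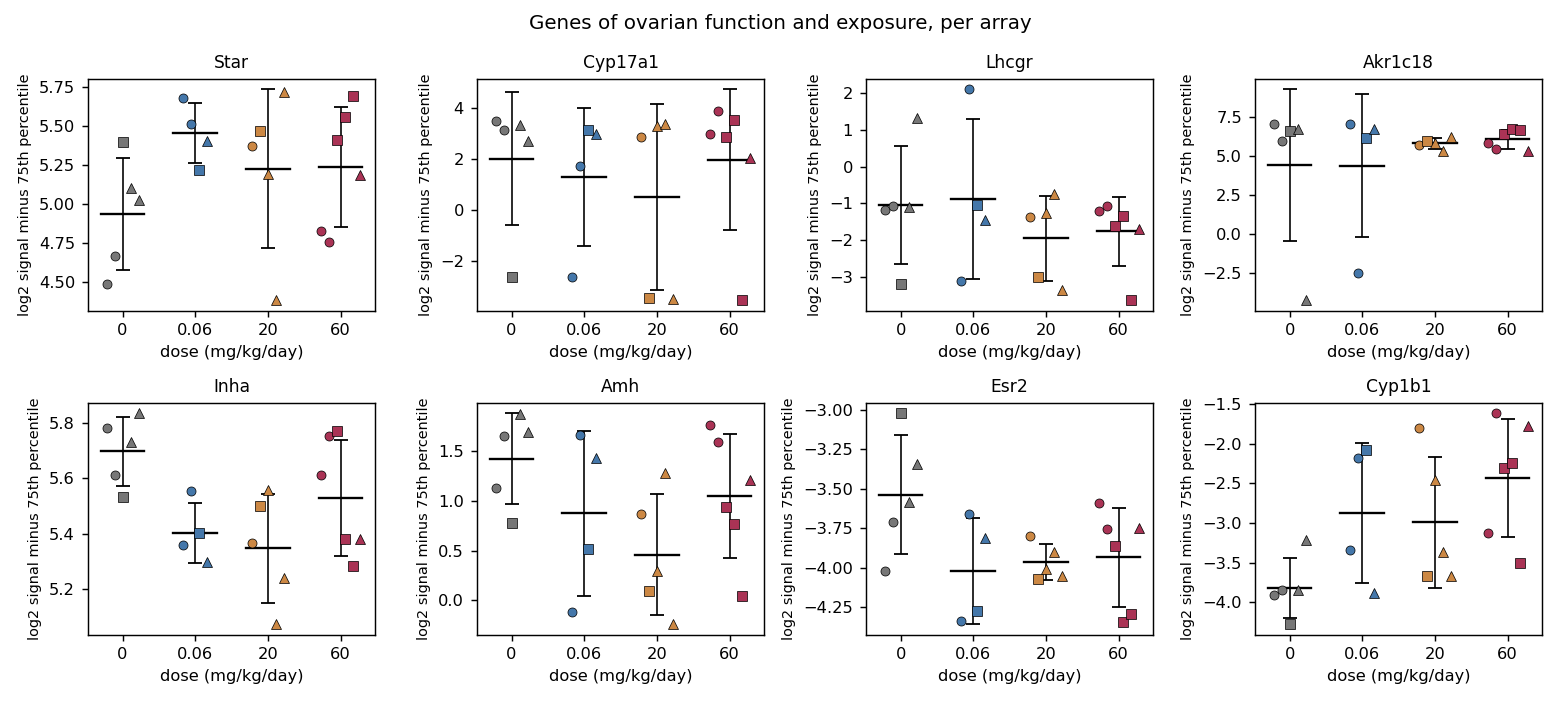
Signal per array for 8 of the fixed genes, as log2 minus the 75th percentile of the array, against dose in mg/kg/day (circles, squares and triangles mark slides 1, 2 and 3; lines are means and bars SD). Cyp17a1 lies between -3.52 and -2.62 on 5 arrays and above 1.71 on the others, and Akr1c18 between -4.23 and -2.48 on 2 arrays.

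Gene lists fixed before the data were examined were set against dose as groups, and fry, a rotation test in limma, called 0 of 38 at every dose. The lowest adjusted p was 0.236 at 0.06, 0.697 at 20 and 0.444 at 60 mg/kg/day, and 2, 1 and 4 lists had an unadjusted p under 0.05. camera with a preset correlation called 8, 11 and 9 lists, of which 0 held with an estimated correlation at any dose. At 0.06 mg/kg/day the 22 measured genes of the corpus luteum list averaged +0.30 ± 0.15 log2 (adjusted p = 0.236 by fry, 0.0809 with an estimated correlation), with 17 above the control mean. The mean on slides 1, 2 and 3 was +0.47, -0.17 and +0.28, so it turned on slide 2, and without replicate 1 at 0.06 mg/kg/day it was +0.18. The 23 steroidogenesis genes averaged +0.18 ± 0.13, +0.09 ± 0.12 and +0.20 ± 0.12 at the 3 doses, and 16, 13 and 16 of them lay above the control mean. Control replicate 5, at -0.51, carried much of this: without it the means were +0.09, -0.01 and +0.10. Akr1c18 belongs to this list and to the corpus luteum list. It lay at -4.23 on that array and at -2.48 on 0.06 mg/kg/day replicate 2, against 5.29 to 7.05 on the others. The steroidogenesis list was not averaged without this gene. The weight of control replicate 5 in its means may therefore be that of this 1 gene, not of the list. On slides 1, 2 and 3 the steroidogenesis list stood at -0.08, +0.33 and +0.41 at 0.06, at +0.09, -0.08 and +0.25 at 20, and at -0.05, +0.25 and +0.40 at 60 mg/kg/day.

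At 20 mg/kg/day the extracellular matrix list averaged +0.26 ± 0.13 log2, with 22 of 28 genes higher, and +0.26, +0.18 and +0.29 on slides 1, 2 and 3. Its members with the smallest p were Col15a1, Bgn and Col1a2, at +0.51 ± 0.15, +0.41 ± 0.13 and +0.49 ± 0.16, and Col1a1 stood at +0.80 ± 0.27. Granulosa cell and growing follicle genes averaged -0.23 ± 0.12, with 16 of 22 lower, and -0.17, -0.02 and -0.33 on the slides. Macrophage and monocyte genes averaged +0.40 ± 0.20, with 16 of 18 higher, and smooth muscle genes +0.25 ± 0.16, with 11 of 12 higher; their values by slide were +0.66, +0.06 and +0.44, and +0.48, +0.05 and +0.12. Oocyte genes averaged -0.41 ± 0.28, with 16 of 18 lower, and erythrocyte genes -0.39 ± 0.17, with 7 of 8 lower. By slide the oocyte list stood at +0.09, -0.16 and -0.95 and the erythrocyte list at -0.42, +0.21 and -0.56, so each turned on 1 slide. Without replicate 3 at 20 mg/kg/day the erythrocyte mean was -0.25, and without control replicate 1 the smooth muscle mean was +0.15. The adjusted p by fry was 0.697 for these 6 lists.

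At 60 mg/kg/day the cell cycle list averaged +0.27 ± 0.12 log2, with 28 of 30 genes higher, and +0.39, +0.06 and +0.45 on slides 1, 2 and 3. Its members Tpx2, Mcm3 and Rrm2 stood at +0.46 ± 0.16, +0.43 ± 0.15 and +0.49 ± 0.18. Macrophage and monocyte genes averaged +0.44 ± 0.20, with 16 of 18 higher: Lyz2 stood at +0.53 ± 0.21, Aif1 at +0.61 ± 0.24 and Cd68 at +0.79 ± 0.32. On slides 1, 2 and 3 this list stood at +0.29, +0.11 and +0.57. The insulin and IGF axis averaged -0.12 ± 0.04, with 13 of 18 lower, and NRF2 targets and antioxidant enzymes +0.14 ± 0.08, with 21 of 27 higher. By slide the insulin and IGF axis stood at -0.12, -0.04 and -0.18, and the NRF2 list at -0.09, +0.21 and +0.33. The adjusted p of these 4 lists by fry was 0.444. With slide as a block the macrophage list was +0.33 ± 0.17 and the NRF2 list +0.13 ± 0.08, and their unadjusted p by fry went from 0.0467 to 0.0861 and from 0.0385 to 0.116. Target genes of the receptors CAR, PXR and AhR averaged +0.0711 ± 0.12, +0.00414 ± 0.11 and -0.00208 ± 0.11 log2 at the 3 doses. With slide as a block these were +0.10, -0.02 and +0.05, and without control replicate 3 they were +0.01, -0.06 and -0.07. On slides 1, 2 and 3 this list stood at -0.01, +0.42 and +0.02 at 0.06, at +0.08, -0.01 and -0.06 at 20, and at -0.02, +0.22 and +0.03 at 60 mg/kg/day. Without replicate 1 at 0.06 mg/kg/day its mean there was +0.16. A mean near 0 does not mean that no member moved. At 60 mg/kg/day 4 of the 20 measured genes had an unadjusted p under 0.05 in limma. Of these 2 were higher, Cyp1b1 among them, and 2 lower, and none passed over the list alone, the lowest adjusted p being 0.0717.

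Against 0 mg/kg/day, single members passed limma where p was adjusted over the list alone. In the apoptosis list Casp6 passed at 0.06 and 20 mg/kg/day, with an adjusted p of 0.00725 and 0.00588, and Fas passed at 20. Fas also passed in the list of p53 targets at 20 mg/kg/day, with an adjusted p of 0.0350, and Mcpt9 passed among granulocyte and mast cell genes at 60, with 0.00922. Over all probes tested none of these passed, the adjusted p being 1.00 for Casp6 at 0.06, 0.929 for Casp6 and Fas at 20 and 0.782 for Mcpt9 at 60. As groups, the apoptosis genes averaged -0.01 ± 0.05 and +0.03 ± 0.04 log2 at 0.06 and 20 mg/kg/day.

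**Figure D3:**
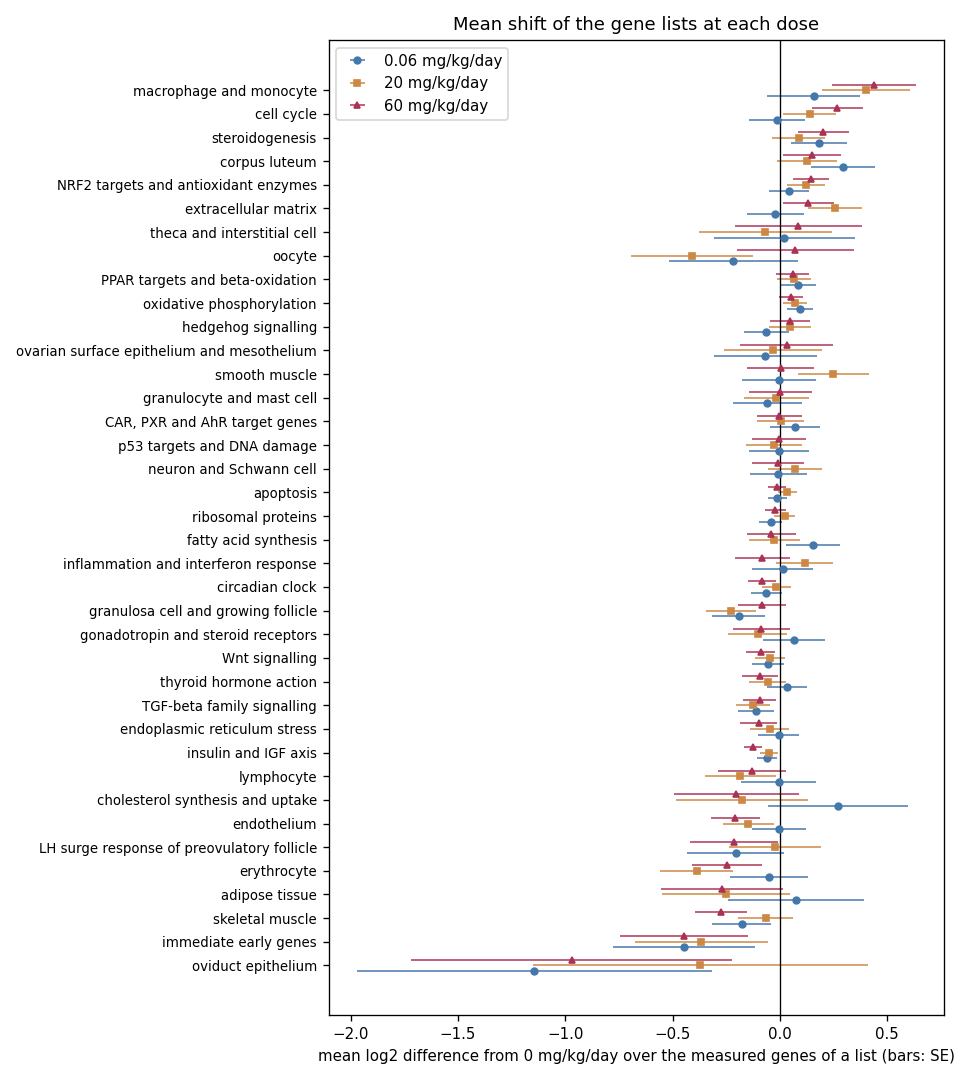
Mean log2 difference from 0 mg/kg/day over the measured genes of each of 38 lists, at 0.06 (circles), 20 (squares) and 60 mg/kg/day (triangles), with bars of 1 SE between animals. fry called 0 lists at each dose, and oviduct epithelium genes had the widest bars.

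Oviduct epithelium genes, which mark tissue next to the ovary, averaged -1.15 ± 0.83, -0.37 ± 0.78 and -0.97 ± 0.75 log2 at the 3 doses, since 2 of the 5 control arrays stood high. Without control replicate 4, 1 of these, they were -0.63, +0.15 and -0.45. By slide the oviduct epithelium list stood at -1.16, +0.02 and -1.73 at 0.06, at -1.38, -0.03 and -0.25 at 20, and at -1.27, +0.25 and -0.37 at 60 mg/kg/day. Immediate early genes averaged -0.45 ± 0.33, -0.37 ± 0.31 and -0.45 ± 0.30. Control replicate 1, at 1.61, carried this: without it the means were -0.12, -0.04 and -0.12. On slides 1, 2 and 3 the immediate early genes stood at -1.14, -0.33 and +0.39 at 0.06, at -1.38, +0.12 and +0.16 at 20, and at -1.04, +0.04 and -0.22 at 60 mg/kg/day. Neither list was called by fry.

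A trend over the order of the doses was called for 0 probes by limma, with 1338 at an unadjusted p under 0.05 and a lowest adjusted p of 0.520. The joint test of all 3 doses called 0, with 738 at an unadjusted p under 0.05. Between doses, limma called 0 probes for 20 against 0.06, with 657 at an unadjusted p under 0.05. It also called 0 for 60 against 0.06, with 565, and 0 for 60 against 20, with 1320 of which 1139 were lower at 60. The share that was lower moved with the setting: 624 of 1272 such probes after quantile normalization, 639 of 1155 with slide as a block and 339 of 510 without slide 3, which carried 3 of the 5 arrays at 20 and 1 of the 6 at 60. With slide as a block the trend, the joint test and these 3 pairs again called 0, with 1366, 1008, 634, 1025 and 1155 probes at an unadjusted p under 0.05. Among the lists, extracellular matrix was +0.28 ± 0.13 log2 at 20 against 0.06 mg/kg/day and the cell cycle list +0.28 ± 0.13 at 60 against 0.06. Without replicate 2 at 0.06 mg/kg/day they were +0.17 and +0.18. By slide the first stood at +0.23, +0.29 and +0.42 and the second at +0.50, 0.00 and +0.42. fry called 0 lists for each pair of doses, and 1, 1 and 0 lists had an unadjusted p under 0.05 for 20 against 0.06, 60 against 0.06 and 60 against 20.

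At 60 against 20 mg/kg/day the oocyte list averaged +0.48 ± 0.27 log2, with 16 of 18 genes higher, 9 of them at an unadjusted p under 0.05. Zp1, Zp2, Zp3 and Zp4, which encode the coat of the egg, stood at +0.87 ± 0.27, +0.96 ± 0.30, +0.77 ± 0.24 and +0.78 ± 0.27. These 4 passed limma adjusted over the list alone, with an adjusted p of 0.0327 for Zp1, Zp2 and Zp3 and 0.0442 for Zp4, and did not pass over all probes tested, with 0.782. Of the 38 lists, 0, 0 and 1 held such a member for 20 against 0.06, 60 against 0.06 and 60 against 20. As a group the oocyte list was not called by fry, with an adjusted p of 0.950, nor with slide as a block, with 0.236 and a mean of +0.70 ± 0.24; its adjusted p with an estimated correlation was 0.881. On slides 1, 2 and 3 it stood at +0.88, -0.005 and +0.94.

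Log2 differences from the shared controls correlated across probes, which are not independent, with r of 0.480 between 0.06 and 20, 0.639 between 0.06 and 60 and 0.547 between 20 and 60 mg/kg/day. Simulated unchanged groups that share a control group gave a mean r of 0.455, 0.476 and 0.503. All their arrays, controls included, were drawn from the residuals of the 20 arrays, so the real control arrays were not kept. The covariance was 0.0355, 0.0514 and 0.0452, against simulated means of 0.0388, 0.0378 and 0.0382, and 54, 25 and 35 of 100 simulations were as large. With separate control arrays for the 2 doses the mean r over 20 fits was -0.0829, 0.0484 and -0.0021. There were 0 called genes to overlap.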

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

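The tests of slide, of failed spots, of time after the hormone surge, of few corpora lutea and of dose were chosen after the values they use had been seen, and the other 2 before. The patterns too were picked after the values per array had been seen, Cyp17a1 and Akr1c18 in place of slide differences and 2200002J24Rikl. Values are log2 unless a unit is given. Of 346 groups of arrays examined 28 held 1 array far from the others of its dose, and these are given dose by dose. Chance gives about 17.3 for independent groups. Lists and single genes overlap here, and many genes were picked by p, so the excess is no test.

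Cyp17a1 lay at -3.52 to -2.62 on 5 of the 20 arrays and at 1.71 to 3.86 on the others. A slide effect is argued against by the 3 slides that hold both kinds of array. Failed spots of 1 probe are argued against by Lhcgr, lowest on the same 5 arrays. Dose as the only cause is argued against by the 1 control array among them. They were 1, 1, 2 and 1 at the 4 rising doses, and whether dose changes how often this occurs was not tested. Fewer theca cells are argued against by 10 other theca and interstitial genes, whose median deviation on these arrays was never below -0.50, though Fabp3, Aldh1a1 and Mgarp among them averaged -1.85, -0.996 and -0.546, so a loss of part of the theca cells stays open. Of the 5 arrays, 4 are among the 5 highest for corpus luteum genes taken without Lhcgr and Akr1c18. The remaining array of those 5 highest, at 0.28, is low in Akr1c18, and arrays low in Akr1c18 had the highest Lhcgr. The 5 arrays low in Cyp17a1 lay at 0.269 to 0.543. These genes include Star and Cyp11a1 and cannot show that corpora lutea were present. A candidate explanation is the time since the surge of luteinising hormone. No group of the design gives cycle stage, so this stays a hypothesis.

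Akr1c18 lay at -4.23 and -2.48 on 2 arrays and at 5.29 to 7.05 on the others. A slide effect is argued against by the 2 slides that hold both kinds of array. Failed spots are argued against by the second probe, lowest on the same 2 arrays, and dose as the only cause by the 1 control among them. Of the 2 arrays, 0 are among the 5 lowest for the other corpus luteum genes. These include Star and Cyp11a1, which are also in the theca and interstitial list. They cannot show that corpora lutea were present, so few corpora lutea stay open. Both arrays had the highest Lhcgr, at 1.32 and 2.10, and the lowest mean of the list of genes answering the hormone surge, at -0.71 and -0.63. What sets them apart stays open.

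Oviduct epithelium genes averaged 2.39 to 2.69 on 3 arrays, 0 mg/kg/day replicates 2 and 4 and 20 mg/kg/day replicate 5, and -0.98 to 0.91 on the others. A slide effect is argued against by the 2 slides that hold both kinds of array, and dose as the only cause by the 2 controls among the 3. Of 12 further epithelial genes written down for the purpose, after related genes had been looked at, 10 were measured, and for 6 all 3 arrays were among the 6 highest, which chance gives for 1.75% of genes. Krt7, Krt19, Elf3, Spint1, Tmprss2 and Rab25 were the 6, and oviduct tissue taken with the ovary may be the source.

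At 0 mg/kg/day, replicate 3 stood apart for Cyp17a1 at -2.62, for RT1-T24-2 at -8.27, for Slc25a2 at -6.44, for Scara5 at -5.53 and for the extracellular matrix list at 0.186. Replicate 4 stood apart for Slbp at -2.40 and for the oxidative phosphorylation list at -0.250, and replicate 5 for Akr1c18 at -4.23.

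At 0.06 mg/kg/day, replicate 1 stood apart for the theca and interstitial list at -0.761, for the corpus luteum list at 0.502 and for targets of CAR, PXR and AhR at -0.213. Replicate 2 stood apart for Akr1c18 at -2.48, the erythrocyte list at 0.490 and the thyroid hormone action list at 0.159. Replicate 3 was low for the insulin and IGF axis at -0.0956, and replicate 5 had a 75th percentile of processed signal of 1552.

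At 20 mg/kg/day, replicate 3 stood apart for the erythrocyte list at -0.744 and for a spread between repeat spots of 9.16%. Replicate 4 was high for the thyroid hormone action list at 0.0917 and for spots well above background at 80.0%. Replicate 5 was low for fatty acid synthesis at -0.315 and for the oocyte list at -0.690.

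At 60 mg/kg/day, replicate 5 carried all 6 of the values that stood apart. These were Cyp17a1 at -3.52, Lhcgr at -3.63, Fam181b at -4.80, the theca and interstitial list at -0.819, the apoptosis list at 0.122 and the Wnt signalling list at 0.106.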

How the results depend on the processing

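The spike-in blocks and the left-out sets of arrays were added after the data were seen. Every count of called genes stayed at 0 under the alternatives run, except for 2 settings. At an unadjusted p under 0.05 and 1.5-fold, which holds no adjustment by construction, the counts were 206, 300 and 532 at the 3 rising doses, 21 for the trend, 216 for 20 against 0.06, 182 for 60 against 0.06 and 442 for 60 against 20. With a replicate block, 2 genes were called for 60 against 20; the cause was not tested. Replicate numbers do not pair the animals: 8 of 27 same-numbered pairs correlate above 0.1, and 1 of 20 arrays correlates best with its own number. Of the 27 pairs 16 share a slide, so the replicate block is partly a slide block. With slide removed their median correlation was -0.0929. Of the lists, quantile normalization called 1 at 0.06 mg/kg/day, corpus luteum, adjusted p 0.0363; the cause was not tested. In the scaling used elsewhere the adjusted p of that list was 0.236, and 0.0809 with an estimated correlation; its mean was -0.17 on slide 2 and +0.18 without 0.06 replicate 1. camera with a preset correlation called 8, 11 and 9 lists, of which 0 held with an estimated correlation. With separate control arrays for the 2 doses the correlations were -0.0829, 0.0484 and -0.0021, since the shared control values are gone by construction. Leaving out each array gave 0 calls, with 447 to 1437, 558 to 2148 and 960 to 2256 probes at an unadjusted p under 0.05 at the 3 doses. The highest counts came without 0.06 replicate 5, 0 replicate 3 and 0 replicate 3, and the lowest without 0 replicate 4, 0 replicate 1 and 0 replicate 1. For the trend they ran from 871 without 0 replicate 1 to 2094 without 0 replicate 3, and for the joint test from 524 without 60 replicate 3 to 1215 without 0 replicate 3. Between doses they ran from 408 without 0.06 replicate 2 to 1454 without 0.06 replicate 5 for 20 against 0.06, from 398 without 0.06 replicate 2 to 1111 without 0.06 replicate 3 for 60 against 0.06, and from 579 without 20 replicate 5 to 2798 without 60 replicate 6 for 60 against 20. Without the 7 arrays low in Cyp17a1 or Akr1c18, 0 were called, the lowest adjusted p at 60 mg/kg/day being 0.0679, against up to 0.975 over all settings. Of the genes of smallest p, 3 of 1849 values turned sign, and of the fixed genes 56 of 1296, and 0 passed. The former were picked by p on these same arrays, so their kept signs are no test of them. Dim probes are limited by signal over background.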

Other observations

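The other splits of the arrays were set before their results were seen, those within slides after the free splits were known. Genes singled out here were chosen after their values were seen. Kit, the receptor through which oocytes and theca cells receive stem cell factor, stood at -0.72 ± 0.44, -1.18 ± 0.41 and -1.04 ± 0.39 log2 (SE) at the 3 rising doses. 2200002J24Rikl, a gene known by a clone name, has 3 probes, well above background on 18, 15 and 12 of the 20 arrays. The first stood at +0.98 ± 0.53, +2.02 ± 0.50 and +2.12 ± 0.48 log2 at the 3 doses and the second at +0.70 ± 0.69, +2.22 ± 0.65 and +2.56 ± 0.63, with 4 and 2 of the 5 controls well above background. The third was well above background on 0 of the 5 controls, which leaves bounds of at least 1.27-fold, 2.89-fold and 2.56-fold higher. Klf6, an immediate early gene, stood at -0.40 ± 0.20, -0.49 ± 0.19 and -0.52 ± 0.18 at the 3 doses, and Cldn5, a tight junction gene of endothelium, at -0.06 ± 0.18, -0.41 ± 0.17 and -0.39 ± 0.16. Klf6 belongs to the immediate early list, whose means control replicate 1 carried, and for Klf6 alone this was not tested. The 3 doses share the same controls. The limma adjusted p of these 4 genes was 1.00 at 0.06, 0.929 at 20 and 0.782 at 60 mg/kg/day.

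Animals of one dose differed most in the oviduct epithelium list, with a pooled SD of 1.23 log2, then in the immediate early genes, with 0.492, the theca and interstitial list, with 0.490, and cholesterol synthesis, with 0.484. Cholesterol synthesis genes spanned -0.78 to 1.23 over the 20 arrays, and oocyte genes -0.69 to 0.88. The lists with the least spread were the insulin and IGF axis, with 0.0682, apoptosis, with 0.0686, and ribosomal proteins, with 0.0794.

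Chance cannot be excluded for the counts of probes, nor for those of lists against 0 mg/kg/day. Counts of lists between doses and members that passed over their list alone were not set against other splits. Among 100 splits of the arrays drawn freely across slides, the real one included, those with as many probes at an unadjusted p under 0.05 numbered 75 at 0.06 mg/kg/day, 49 at 20 and 30 at 60. The real counts of 710, 1066 and 1464 compare with 6890, 4186 and 4585 in the highest other split. For the trend 32 splits gave as many as 1338, the highest 7409, and for the joint test 55 gave as many as 738, the highest 3006. Between doses, 60 splits reached 657 for 20 against 0.06, 72 reached 565 for 60 against 0.06 and 12 reached 1320 for 60 against 20, with 4927, 3629 and 4097 the highest. For lists at an unadjusted p under 0.05, 67 splits reached 2 at 0.06 mg/kg/day, 73 reached 1 at 20 and 28 reached 4 at 60, with 11, 9 and 11 the highest.

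Splits that keep the number of arrays of each group on each slide, fitted with slide as a block, do not exclude chance either. Of all 36, 60 and 72 such splits, 26, 11 and 13 had as many probes at an unadjusted p under 0.05 as the real 970, 1427 and 1339 at the 3 doses, against 4070, 2846 and 2795 in the highest other split. For the trend 25 of 100 reached 1366, the highest 2796, and for the joint test 54 of 100 reached 1008, the highest 3467. Between doses, 21 of 24 reached 634 for 20 against 0.06, 21 of 48 reached 1025 for 60 against 0.06 and 8 of 48 reached 1155 for 60 against 20, with 3237, 3378 and 2649 the highest. For lists, 23 of 36 reached 2 at 0.06 mg/kg/day, 12 of 60 reached 3 at 20 and 24 of 72 reached 2 at 60, with 6, 6 and 7 the highest.

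Splits with several times the real count point to a structure of the arrays. In the highest split for 0.06 mg/kg/day, slide 3 gave 3 of the 4 arrays of one group and 0 of the 5 of the other, and arrays low in Cyp17a1 gave 0 and 2. For 20 mg/kg/day slide 3 gave 4 of 5 and 1 of 5, and arrays low in Cyp17a1 gave 0 and 3. For 60 mg/kg/day and for 60 against 0.06 the 2 kinds also lay in opposite groups. For 60 against 20 they lay in the same group: slide 3 gave 0 of 5 and 4 of 6, and arrays low in Cyp17a1 gave 0 and 3. For 20 against 0.06 slide 3 gave 0 of 5 and 4 of 4, and arrays low in Cyp17a1 gave 2 and 1. On slide 3, 4827 probes differed in limma from the mean of the other slides, 4314 of them higher, among them 15.3% of the named and 30.4% of the unnamed probes.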
